A study of Equus caballus with 2 samples.

How the data were processed

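DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in 1 equine sarcoid library and 1 library of tumour-distant skin, both from horse 1. RRBS cuts DNA with the enzyme MspI at CCGG sites, keeps short fragments and converts unmethylated cytosines with bisulfite, so that a cytosine read as C counts as methylated and one read as T as unmethylated. Per the labels' protocols, libraries were made after Illumina's RRBS guide from tissue DNA and each was sequenced on 1 lane with 75 bp single-end reads. BSMAP, FastQC and methylKit were named per the submitters' processing notes, without versions or settings. The genome build was not given in the sources used here, and coordinates are printed as the deposited files give them.

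The deposited file of each library lists, per the file headers, a read count (coverage) for the cytosine of a CpG on each strand, with the percent of those reads showing C and T to 1 decimal. Files listed chromosomes 1 to 31 only. Coverage was under 5 reads at 0.112% of the cytosines listed in skin and 0.113% in sarcoid, so most cytosines of lower coverage had been left out before deposit. The authors also deposited a table of p-values, q-values and methylation differences per CpG, which held chromosome 1 only. Its p-value equalled a two-sided Fisher's exact test on the reads of both libraries within 0.0001 at 98.6% of CpGs, and its differences were skin minus sarcoid.

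Methylated reads were coverage times the percent of C, rounded to a whole number. The product lay further from a whole number than rounding allows (0.0005 of the coverage) at 0.567% of cytosines in skin and 0.543% in sarcoid, and those were kept. Both strands of a CpG were summed. CpGs with at least 10 reads in both libraries were used, apart from the 0.1% of shared CpGs with most coverage in either library (over 574 reads in skin or 403 in sarcoid), which removed 1324 and left 875729. Their median coverage was 41 reads in skin and 31 in sarcoid.

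Methylation differences are sarcoid minus skin throughout, in percentage points. Mean differences have 95% intervals from 1000 bootstrap draws of 1 Mb blocks of the genome. CpG sites, and 1 kb tiles with at least 3 such CpGs, were tested with a two-sided Fisher's exact test on reads and Benjamini-Hochberg adjustment, and called at q below 0.01 with a difference of at least 25 points. There were no replicates: such a test compares these 2 libraries and not the conditions, and intervals cover counting error or positions in the genome, not animals. PCR reads without molecular identifiers are not independent molecules, and a read over several CpGs counts once for each, so p-values of tiles are too small. Wilson 95% intervals are given for the level of a tile. The reads of a tile are summed over its CpGs, so these intervals are too narrow for the same reason. The same test between the strands of 1 CpG within 1 library was planned as a comparison without a tissue difference.

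The tiles named were, by a rule fixed before the data were examined, the 5 with the largest rise and the 5 with the largest fall among called tiles. A further 3 in each direction among tiles with over 20 CpGs were chosen after their values were seen. Promoters, CpG islands, repeats and gene lists had been planned, but no genome or annotation of the build of the files was at hand. The number of CpGs listed per 1 kb tile stood in for sequence context. Depth per chromosome was the log2 ratio of sarcoid to skin reads at shared CpGs, adjusted for the number of CpGs per tile and set to 0 at the median chromosome. Sets of chromosomes were compared by two-sided permutation tests of 100000 draws. Intervals of gaps between sets came from 1000 bootstrap draws of chromosomes within each set.

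The analysis used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. It was tested on simulated data with the real coverage at 875729 sites. Reads were drawn independently around 1 pooled level per CpG, without copies of molecules or differences between strands. The counts of false calls below are therefore a best case and not the rate in the real data. With 20000 sites changed, 11.0% of those changed by 30 points and 57.0% of those changed by 50 points were called, with 10 calls among unchanged sites. With 2000 sites changed, 4.9% and 41% were called, with 1 call among unchanged sites. Among 103489 simulated tiles, 64.5% of 200 tiles changed by 30 points passed the q threshold, with no limit on the difference. Of the unchanged tiles, 40 were called with both thresholds, more than a q below 0.01 would allow. Calls of tiles can thus hold more false ones than q states. Simulated reads were independent, so copies and reads over several CpGs cannot have given these calls. A tile level weighs CpGs by reads. Where CpGs of unlike level have unlike coverage in the libraries, a tile can therefore differ without a change at any CpG. How many calls arose in this way was not measured. A simulated depth gap of 0.379 (log2) on 5 chromosomes was recovered as 0.378. Alternatives covered the coverage limits, thinning to 10 reads, the strands, the thresholds, the model, tile and window size and the chromosomes included.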

Results

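Equine sarcoid is a fibroblastic skin tumour of horses that is associated with bovine papillomavirus infection. DNA methylation was profiled by RRBS in 1 sarcoid and in 1 sample of skin taken away from the tumour of the same horse, to ask where methylation of the tumour differed from that of skin. The skin library held 1701575 cytosines of 1203704 CpGs with 48650606 reads over cytosines in total, and the sarcoid library 1655782 cytosines of 1147734 CpGs with 35970547. Median coverage per CpG was 30 reads in skin and 24 in sarcoid. Both strands were listed at 41.4% of CpGs in skin and 44.3% in sarcoid. Of 1263512 CpGs listed in either library, 1087926 were in both, and 875729 passed the coverage limits and entered the comparison. There was 1 library per tissue and no replicate, so differences describe these 2 libraries.

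Methylation was slightly lower in the sarcoid than in the skin across the genome. The mean level over the 875729 CpGs was 43.9% in skin and 42.7% in sarcoid, a difference of -1.28 points (95% interval -1.41 to -1.14). The mean was lower in the sarcoid on 31 of 31 chromosomes, with a standard deviation over chromosomes of 0.662 points and an interval below 0 on 26 of them. Of single CpGs, 40.1% had a lower level in the sarcoid, 36.0% a higher level and 23.9% an equal level, and Pearson's correlation of the libraries across CpGs, which are not independent replicates, was 0.919. Weighted by the reads of each library the difference was -2.10 points, and it was -2.33 points when each library kept every CpG with 10 reads. These values rest on unlike weights or unlike CpGs in the libraries, so they can also reflect coverage. Other settings, chosen after seeing the data, made the difference smaller. It was -1.04 points at CpGs with both strands covered in both libraries, and -0.871 where those strands were less than 30 points apart. Without the chromosomes of deeper sarcoid coverage it was -0.936 points.

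More CpGs had little or no methylation in the sarcoid than in skin. The share of CpGs at a level of at most 20% was 39.9% in skin and 41.8% in sarcoid, a difference of 1.85 points (interval 1.67 to 2.01), and at an equal depth of 10 reads per CpG it was 42.7% and 44.6%. The share at 30% to 70% differed by -0.385 points and the share at or above 80% by -0.477 points. At 10 reads per CpG these differences were larger, at -0.995 and -0.987 points. CpGs were also placed in classes by their level in 1 library, with its reads split at random into equal parts, one for the class and one for the difference, at CpGs with at least 20 reads in that library. Classed by skin (748916 CpGs), CpGs at 40% to 60% differed by -0.724 points (interval -1.09 to -0.367) and those at 60% to 80% by -4.50 points (-4.79 to -4.20). Classed by sarcoid (648673 CpGs), a setting added after seeing the data, the same classes differed by -5.55 points (-5.90 to -5.19) and -0.398 points (-0.688 to -0.123), so both were lower in the sarcoid either way. The direction in the other classes depended on the library that gave the class. CpGs above 80% differed by -3.14 points classed by skin and 3.71 points classed by sarcoid, those at 20% to 40% by 2.26 and -9.14 points, and those below 20% by 0.384 and -1.97 points. Copies of 1 molecule can fall into both parts of the reads, so the split does not remove all sampling error.

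At single CpGs, decreases outnumbered increases by 1.98 to 1. Of 875729 CpGs, 24863 (2.84%) were called by Fisher's exact test between these 2 libraries, of which 16509 were lower in the sarcoid and 8354 higher, so 66.4% of calls were decreases. CpGs with a skin level of at least 80%, which have no room for a rise of 25 points, held 8017 of the decreases, and CpGs between 20% and 80% held 8492 decreases and 6296 increases. Of 349712 CpGs with a skin level of at most 20%, 2058 (0.588%) rose. Chromosomes 5, 6, 7, 12, 18, 21, 22, 25, 28 and 29, on which the sarcoid library was deeper, held 33.4% of the CpGs tested, 50.7% of the decreases and 40.9% of the increases, called at unequal depth. Without these chromosomes, and with q adjusted anew, 11922 of 583430 CpGs were called, 7446 lower and 4476 higher, and the mean difference was -0.936 points. With q adjusted over all chromosomes, 8145 of these CpGs were lower and 4938 higher. Of the CpGs covered on both strands in both libraries, a smaller set, 11247 of 254377 (4.42%) were called, and of those with strands less than 30 points apart 10113 of 215095 (4.70%). Thinned to 10 reads per CpG, where depth limits the test, 0 sites were called, with 24582 at an unadjusted p below 0.05. A logistic model with the overdispersion seen between strands (factor 5.54), which includes the systematic differences between strands, called 0, with 11294 below 0.05. Both of these counts are under a 0.05 share of the 875729 CpGs, so neither shows an excess of small p-values. With all reads, Fisher's exact test gave 119597 CpGs at an unadjusted p below 0.05.

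Of 103489 tiles of 1 kb tested, 6610 (6.39%) were called, 4250 lower in the sarcoid and 2360 higher, or 1.80 to 1. Unlike coverage of the CpGs of a tile in the 2 libraries can add to these calls, to an extent that was not measured. With reads divided by the CpGs per read, so that a read counts about once, 3409 tiles were called, 2335 lower and 1074 higher. Read numbers of the tiles named below are sums over their CpGs, so their Wilson intervals are too narrow. The largest decrease was on chromosome 24 from 38145001 to 38146000, where methylation fell from 93.9% (Wilson 95% interval 80.4 to 98.3) over 33 reads in skin to 7.69% (2.65 to 20.3) over 39 reads in the sarcoid, at 3 of 8 listed CpGs (q = 5.08e-13). At a minimum of 5 reads per CpG that tile differed by -47.2 points, less than the chromosome 28 tile named next, at -80.3 points. On chromosome 28 from 39902001 to 39903000 the level fell from 82% to 1.67% over 5 CpGs. Further decreases were seen on chromosome 14 from 26515001 to 26516000, from 83.9% to 10%, and on chromosome 19 from 2836001 to 2837000, from 87.8% to 14.1%. A tile of chromosome 13 from 4496001 to 4497000 fell from 82.6% to 9.09%. The largest increase was on chromosome 17 from 25271001 to 25272000, where the level rose from 15.9% (interval 10.5 to 23.2) over 126 reads to 93.3% (84.1 to 97.4) over 60 reads at 3 CpGs (q = 1.80e-23). Another tile of chromosome 13, from 4738001 to 4739000, rose from 23.1% to 96.6%, and chromosome 21 from 52498001 to 52499000 rose from 23.2% to 93.0%. Levels rose from 15.6% to 84.3% on chromosome 6 from 64435001 to 64436000, and from 22% to 90% on chromosome 8 from 31553001 to 31554000, a tile no longer called with reads divided in that way (q = 0.0149). The tiles held 3 to 5 tested CpGs each, and 3 of the 10 lay on the chromosomes of deeper sarcoid coverage. Only 2 of the 10 held CpGs with 10 reads on both strands, none of them with strands 30 points or more apart (count 0). Genes at these positions are not named, since no annotation of the build was used here.

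**Figure D1:**
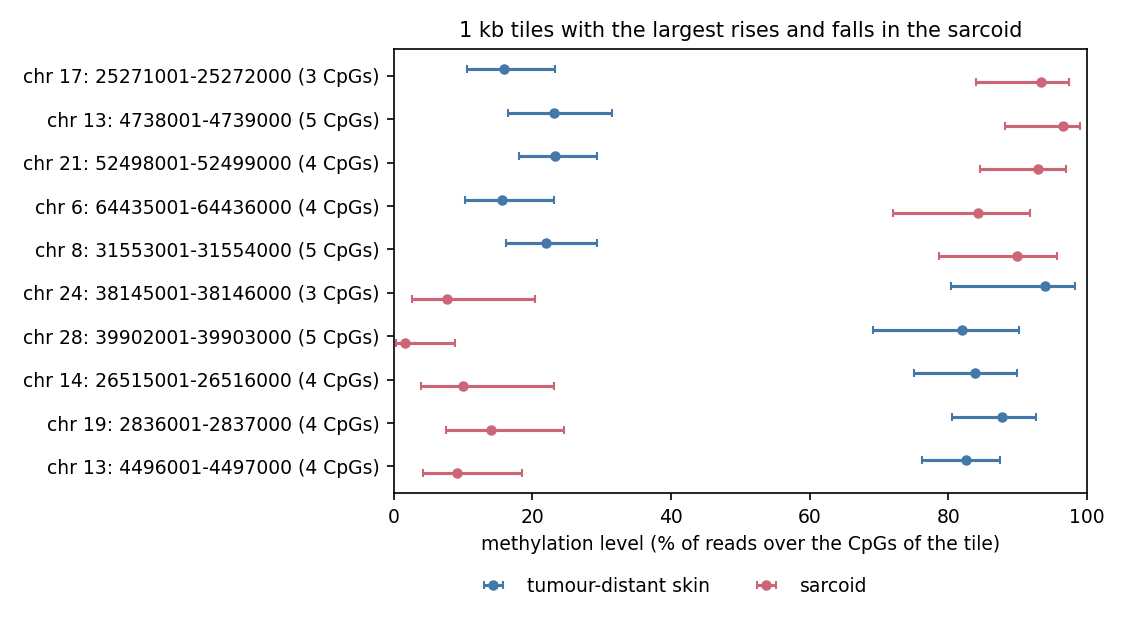
Methylation level (x axis, percent of reads over the CpGs of the tile) of the 10 tiles of 1 kb with the largest rises and falls, in tumour-distant skin and in sarcoid, 1 library each; points are levels, bars are Wilson 95% intervals and labels give chromosome, position and number of tested CpGs. Levels go from 15.9% in skin and 93.3% in sarcoid on chromosome 17, at the top, to 82.6% and 9.09% on chromosome 13, at the bottom. The tiles were selected for large differences. Bars are too narrow, since a read over several CpGs counts once for each.

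In percentage points, the difference was largest in CpG-poor tiles and smallest in CpG-dense tiles. Skin levels were also lower in denser tiles, which leaves less room for a decrease. Density and starting level were therefore not separated. In tiles listing 5 or fewer CpGs the mean was 59.8% in skin and 57.8% in sarcoid (difference -1.97 points, 95% interval -2.12 to -1.83), lower on 31 of 31 chromosomes. Tiles with 21 to 40 CpGs had means of 23.9% and 23.2% (-0.750 points, lower on 23 chromosomes), and tiles with over 40 CpGs 12.4% and 12.2% (-0.267 points, interval -0.515 to -0.017), lower on 20 chromosomes. Tiles with 6 to 10 and with 11 to 20 CpGs lay between, at -1.36 and -1.30 points. The ratio of decreased to increased CpGs was 2.35 in the sparsest class and 1.42 in the densest. Of 10120 tiles with over 20 listed CpGs, 6482 (64.1%) had a level of at most 20% in both libraries. Among the 6601 such tiles of low methylation in skin, 30 (0.454%) were called higher in the sarcoid, with a difference of at least 25 points, and among the 6663 of low methylation in the sarcoid, 45 (0.675%) were called lower than in skin.

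Of all 10120 dense tiles 253 were called, 166 lower and 87 higher in the sarcoid. The 6 described next, of which 4 lay on the chromosomes of deeper sarcoid coverage, were chosen after their values were seen. Their reads too are sums over CpGs, which makes their intervals too narrow. On chromosome 5 from 32270001 to 32271000, the level over 32 CpGs rose from 8.59% (interval 7.44 to 9.91) over 1990 reads to 56.3% (54.0 to 58.6) over 1746 reads, with 31 of the 32 CpGs higher and 26 called singly. A tile of chromosome 1 from 83552001 to 83553000 rose from 12.6% to 75.2% over 11 CpGs, and one of chromosome 5 from 58150001 to 58151000 from 6.39% to 55.8% over 11 CpGs. On chromosome 12 from 28438001 to 28439000, 36 of 36 CpGs were lower in the sarcoid, and the level fell from 50.5% (48.1 to 52.8) over 1759 reads to 4.57% (3.69 to 5.64) over 1773 reads. Chromosome 6 from 26570001 to 26571000 fell from 70.8% to 13.8% over 18 CpGs, of which 17 were lower, and chromosome 15 from 980001 to 981000 from 52.4% to 6.52% over 21 CpGs. Strands lay at least 30 points apart at 2 CpGs of the chromosome 5 tile from 32270001, 3 of the chromosome 6 tile and 2 of the chromosome 12 tile.

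**Figure D2:**
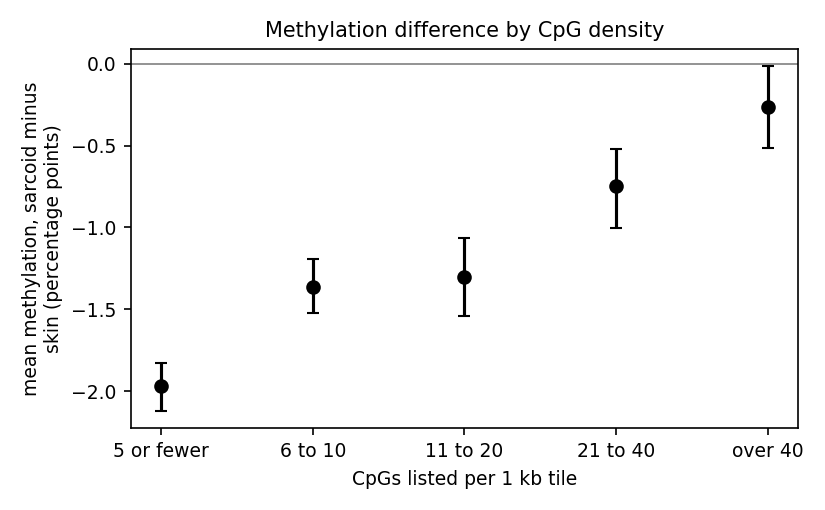
Mean methylation difference, sarcoid minus skin (y axis, percentage points), by the number of CpGs listed per 1 kb tile (x axis); points are means over CpGs and bars are 95% bootstrap intervals over 1 Mb blocks. The difference goes from -1.97 points at 5 or fewer CpGs to -0.267 at over 40.

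The size of the difference varied between chromosomes. The largest differences were -2.91 points on chromosome 25 (interval -3.76 to -1.98), -2.90 on chromosome 12 (-3.56 to -2.13) and -2.38 on chromosome 7 (-3.01 to -1.43). The smallest were -0.355 on chromosome 20 (-0.800 to 0.104) and -0.381 on chromosome 23 (-0.878 to 0.195). The 10 chromosomes of deeper sarcoid coverage had a mean difference of -1.84 points (range -2.91 to -0.746), against -0.938 points (-1.69 to -0.355) on the other 21. On those 10, 2.86% of CpGs decreased and 1.17% increased, against 1.40% and 0.846% on the others, called at the unequal depth of these chromosomes. At an equal 10 reads per CpG, within classes of CpG density and skin level, 6.23% of CpGs on the 10 chromosomes and 4.99% on the others were at least 40 points lower (permutation p = 1e-05, the smallest these permutations can give; adjusted 7.00e-05 over 7 measures). For CpGs at least 40 points higher the shares were 3.67% and 3.55% (gap 0.116, interval -0.0587 to 0.289, permutation p = 0.221). An excess of increases was thus not detectable at equal depth. With 10 reads, sampling alone puts some unchanged CpGs past 40 points. These shares are therefore not shares of changed CpGs, and only their gaps compare the sets. Depth of the 10 chromosomes in the sarcoid relative to skin was 0.228 to 0.334 (log2) above that of the median chromosome, and it was -0.115 to 0.117 on the others.

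**Figure D3:**
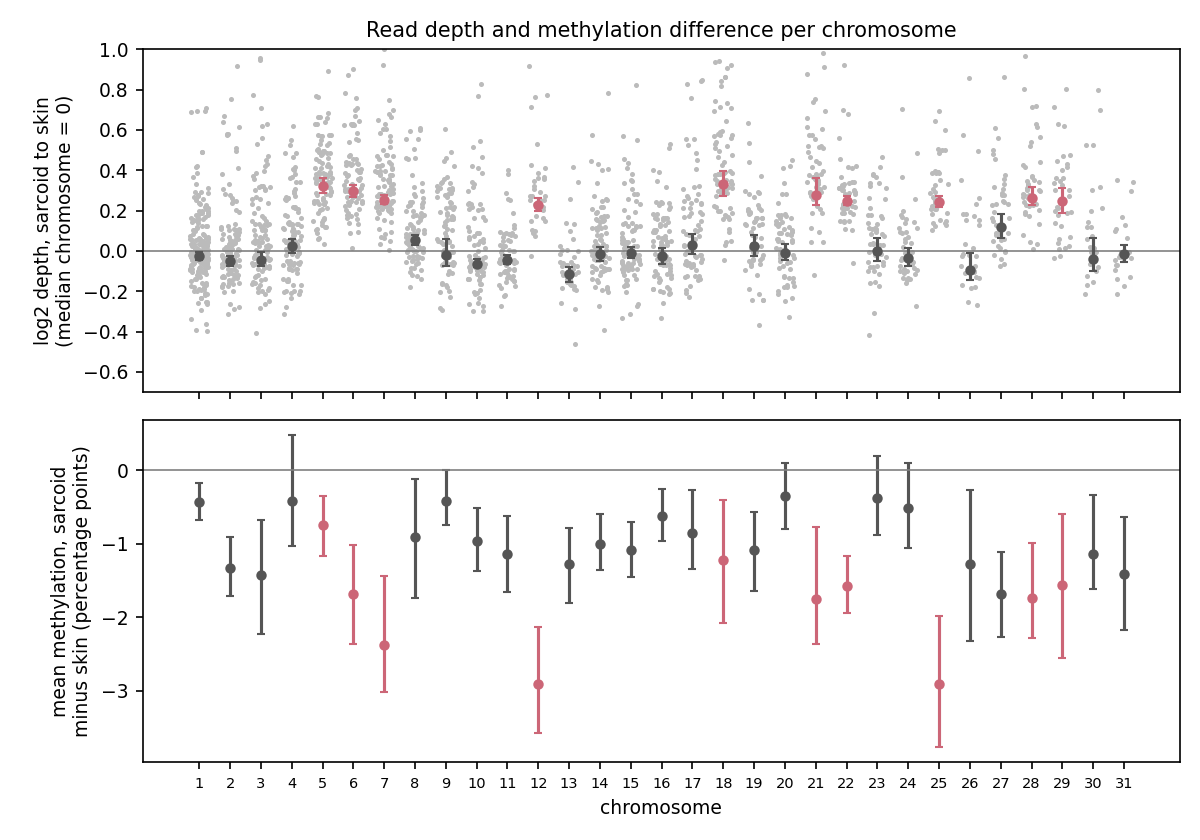
Upper panel, log2 read depth of sarcoid to skin per chromosome (y axis) with the median chromosome at 0, grey dots being 1 Mb windows (6 windows lie outside the axis); lower panel, mean methylation difference (y axis, percentage points); x axis, chromosome; points are chromosome values with 95% bootstrap intervals over 1 Mb blocks, red for the 10 chromosomes of deeper sarcoid coverage. Red points lie between 0.228 and 0.334 in the upper panel and between -2.91 and -0.746 in the lower.

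Most windows of 1 Mb had a lower mean in the sarcoid, and some had a higher one. Of 1978 windows with at least 50 CpGs, 1333 (67.4%) had a lower mean in the sarcoid, with a median difference of -0.751 points; 55 windows differed by less than -5 points and 18 by more than 5. The largest positive difference was on chromosome 21 from 20000001 to 21000000, where the mean of 139 CpGs was 19.7% in skin and 38.1% in sarcoid, with 36 CpGs called higher and 0 lower. Differences of 11.4 points on chromosome 2 from 115000001 to 116000000 and of 10.2 points on chromosome 16 from 26000001 to 27000000 came with 22 and 28 CpGs called higher and 0 lower. On chromosome 4 from 58000001 to 59000000 the mean was 16.7% in skin and 25.5% in sarcoid, with 136 CpGs higher and 33 lower. The largest negative differences were on chromosome 15 from 85000001 to 86000000, with 66.0% in skin and 56.0% in sarcoid over 143 CpGs, and on chromosome 1 from 167000001 to 168000000, with 71.7% and 62.8% over 60 CpGs. On chromosome 6 from 7000001 to 8000000 the mean over 844 CpGs was 53.2% and 44.5%, with 65 CpGs lower and 9 higher.

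The strands of a CpG were compared within each library, a comparison planned as a measure of calls made without a tissue difference. Strands differed systematically, so these rates are no such measure and are given as values. In skin 9.33% of 345082 CpGs were called between their strands, and in sarcoid 14.0% of 341796, against 1.25% of 255098 between sarcoid and skin on the plus strand alone. With at least 20 reads per strand the shares were 5.75% and 13.1%, so over the CpGs of each library the sarcoid had more strand differences. At 254426 CpGs covered on both strands in both libraries, strands lay at least 30 points apart at 13.2% in skin and 13.3% in sarcoid, where sampling of reads gave 1.27% and 1.34%. At these shared CpGs the strand differences of the libraries had a correlation of 0.879 across CpGs. Where strands were apart, the lower strand had a mean of 7.81% in skin and the higher strand 78.3%. Of neighbouring CpGs with strands apart, pairs with the plus strand higher at the first and the minus strand higher at the next lay within 75 bp of each other in 94.5% of 13281 pairs in skin and 92.9% of 13038 in sarcoid. Pairs in the opposite order did so in 1.21% of 13259 and 1.48% of 13013. Merged levels of such CpGs therefore average a pair of unlike strands in both libraries. The mean tissue difference was -1.94 points in the 39288 CpGs with strands apart in either library and -0.872 points (interval -1.03 to -0.723) in the other 215138. With strands kept as strata of a Mantel-Haenszel test, a setting chosen after seeing the data, 27039 CpGs were called, and 23573 of the 24863 were among them.

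**Figure D4:**
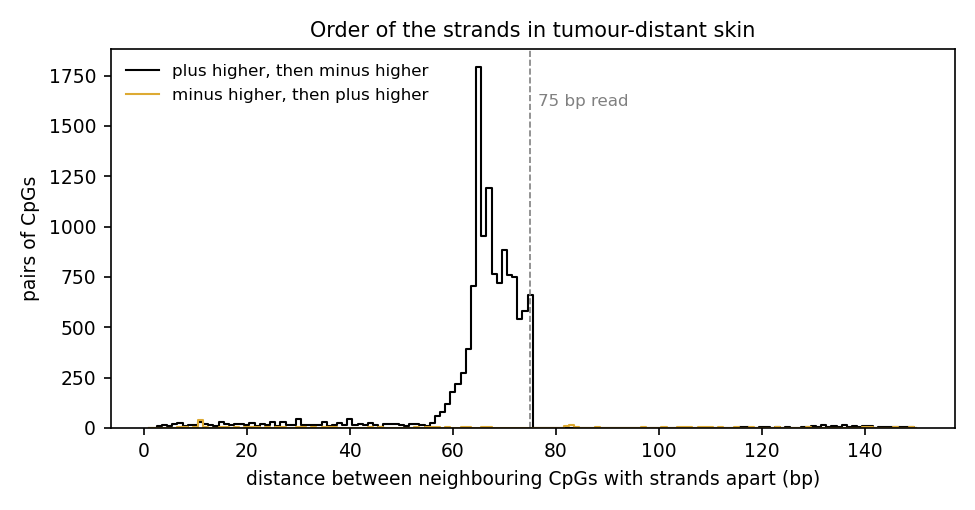
Number of pairs of neighbouring CpGs with strands at least 30 points apart in tumour-distant skin (y axis) by their distance (x axis, bp), for a CpG higher on the plus strand followed by one higher on the minus strand (black) and for the opposite order (yellow). Of the first kind 87.5% lie 57 to 75 bp apart, and 8 pairs lie 76 to 94 bp apart.

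The authors' deposited table tested 74187 CpGs of chromosome 1. With its own q-values below 0.01 and a difference of at least 25 points, 1072 CpGs were called, 632 lower and 440 higher in the sarcoid. The calls made here on chromosome 1, with q adjusted over all 875729 CpGs of the genome, numbered 1077 of 59205, 634 lower and 443 higher. In both sets were 1040 CpGs (97.0% of the authors' calls). Both sets rest on the same reads and nearly the same p-values, so this overlap was largely built in. Their q-values were adjusted over unlike sets of CpGs, so the near-equal totals are not comparable. On all 74187 CpGs with Benjamini-Hochberg adjustment within the chromosome, 854 were called, against the authors' 1072 on the same CpGs. The set of CpGs alone therefore does not account for the authors' number, and the way their q-values were adjusted was not given.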

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

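All tests in this part were chosen after the depth of the chromosomes had been seen; the results of the tests of the skin library alone, of the strands and of the mixture of cells had not been seen when those tests were chosen, though that of the mixture replaced an earlier one, already seen, on shares of CpGs changed by at least 40 points. Read depth was outside the methylation comparisons, and on 10 whole chromosomes the sarcoid library was deeper, relative to skin, than on the rest. The log2 depth of sarcoid to skin, with the median chromosome at 0, was 0.322 on chromosome 5, 0.295 on chromosome 6, 0.253 on chromosome 7, 0.228 on chromosome 12 and 0.334 on chromosome 18. It was 0.278 on chromosome 21, 0.249 on chromosome 22, 0.241 on chromosome 25, 0.261 on chromosome 28 and 0.249 on chromosome 29. The highest of the other 21 chromosomes was chromosome 27 at 0.117, and the mean gap between the sets was 0.288 (1.22-fold, 95% interval 0.259 to 0.318). The sets were split at the largest step in these same depths, so a gap between them was fixed in advance. Its interval describes the spread over chromosomes and does not test the gap.

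A bias by CpG density could give such a gap only if it closed within classes of density, and the smallest gap over the 5 classes was 0.268 (log2), for a set of 10 chromosomes that was the same when chosen without adjustment for density. An imbalance of the skin library was also argued against, since the skin library alone had a gap of -0.0239 (interval -0.0461 to -0.0008) and the sarcoid library alone one of 0.265. Extra copies of these whole chromosomes in a share of sarcoid cells stay open, as does a loss of the other 21, which relative depth cannot separate from a gain of the 10. On each of the 10 at least 85.3% of 1 Mb windows lay above the median window of the other chromosomes, but the 10 were chosen for their depth, and chromosome 27, not among them, had 79.5%, past the bound of 75% set for that test. Tissue, library and lane were the same split here, so a fault of the sarcoid library that follows whole chromosomes stays open and was not tested.

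The same 10 chromosomes lost more methylation, with a gap of -0.907 points to the others (permutation p = 9.00e-05, Benjamini-Hochberg adjusted 0.00021 over 7 such measures), although chromosomes 5, 6, 18, 22 and 29 lay within the range of the others (-1.69 to -0.355). These values argue against the mix of CpGs and the strand differences as the whole of it: within classes of CpG density and skin level the gap was -0.810 (permutation p = 5.00e-05), and in CpGs with strands less than 30 points apart it was -0.680 (permutation p = 0.00026). More tumour DNA in the mixture on these chromosomes stays open: CpGs below 40% in skin rose less there, by 0.442 against 0.950 points (gap -0.509, interval -0.781 to -0.240), where more tumour DNA was predicted to enlarge the rise, but that prediction was wrong to take the rise as given, since CpGs of such levels differ by 0.384 and 2.26 points classed by skin and by -1.97 and -9.14 points classed by sarcoid. Without chromosomes 7, 12 and 25, which differed most, the gap was -0.528 points. A lower methylation of any extra copies themselves, or a sarcoid cell population with both features, may also be behind the link as a biological hypothesis; neither was tested, and library and lane stay confounded with tissue.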

How the results depend on the processing

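Chosen only after the data were seen were the settings on CpGs covered on both strands, strands less than 30 points apart, strands as strata, the chromosomes left out, methylated read numbers that were not whole, the logistic model without overdispersion, the classes from sarcoid reads and those on the sets of chromosomes. With classes by level taken from the sarcoid reads, 3 differences reversed, to -1.97 points below 20%, -9.14 at 20% to 40% and 3.71 above 80%, and 2 moved, to -5.55 at 40% to 60% and -0.398 at 60% to 80%; the cause was not tested. No other result reversed under the alternatives run. The mean difference moved to -1.45 points at a minimum of 30 reads, -2.10 weighted by the reads of each library and -2.33 over every CpG of each library. In the smaller set of CpGs covered on both strands in both libraries it was -1.04, with 11247 sites (4.42% of those tested), 1748 tiles (5.02%), 65.1% of windows lower, a depth gap of 0.240 and differences of -1.63 and -1.19 points in the 2 sparsest density classes. Keeping of these only CpGs with strands less than 30 points apart gave -0.871, 10113 sites (4.70%), 1608 tiles (5.62%), 60.9% of windows, a depth gap of 0.239 and -1.68, -1.06 and -0.948 points in the 3 sparsest classes. The lower counts of sites and tiles thus came mostly from the smaller set; for the other moves the cause was not tested. Without the deeper chromosomes the mean difference was -0.936, with 11922 sites (2.04% of those tested) and 4025 tiles, q being adjusted anew. The CpGs left out differed by -1.98. Sites numbered 42810 at q below 0.05, by construction, and 0 when thinned to 10 reads, where depth limits the test, and 0 with overdispersion from the strands (factor 5.54), a factor that includes the strand differences at fragment ends. Tiles numbered 2801 at a minimum of 30 reads, 3836 at 5 kb, 884 with at least 10 CpGs, 17125 at a difference of 10 points and 3409 with reads divided by CpGs per read (median 3.4). The strand comparison in skin gave 5.75% at 20 reads per strand, and 79.1% of 5 Mb windows were lower; for these, the mean differences and the tile counts the cause was not tested. Among site and tile settings with calls, decreases made up 59.3% to 68.7% of calls. Of 128 checks on the 16 named tiles, 50 gave no value, as too few CpGs were left at a minimum of 20 or 30 reads or with both strands covered. Of the other 78, 77 kept direction and threshold, and 1, chromosome 8 from 31553001 with reads divided, missed the threshold (q = 0.0149). Many of these checks were weak. Leaving out the upper coverage limit or dividing reads left every difference of a named tile unchanged. Each setting on strands gave a value for only 3 tiles, all chosen after their values were seen. Size could change within a kept check, as on chromosome 24, from -86.2 to -47.2 points at a minimum of 5 reads. No paired analysis was possible because there was 1 library per tissue, both from horse 1. Promoters, gene lists, CpG islands and repeats were not run, having no annotation of the build, and autosomes alone moves nothing, as only chromosomes 1 to 31 are listed.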

Other observations

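The tests of the strands in this part were chosen after the pattern had been seen. The 1324 CpGs left out for their high coverage had a mean of 50.9% in skin and 50.1% in sarcoid, a difference of -0.798 points (interval -1.66 to -0.009). CpGs listed on the same single strand in both libraries numbered 364370 and differed by -1.58 points.

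Strands of a CpG lay at least 30 points apart in both libraries at a rate that sampling of reads does not give, being at least 9.97 times the simulated rate in each. Strand-specific methylation of the tissue should show no fixed order of strands along the genome, whereas at most 1.48% of minus-then-plus pairs of neighbours lay within 75 bp, against at least 92.9% of plus-then-minus pairs. This order and the limit at the read length are consistent with cytosines filled in without methylation when MspI ends are repaired, and reached at the far end of fragments of up to 75 bp. The hypothesis is technical and could lower merged levels near such ends, in each library to an extent that was not measured. Trimming of reads was not given in the sources used here.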
